A study of Mus musculus with 15 samples.

How the data were processed

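Liver RNA of 15 mouse pups on postnatal day 1 was measured on Agilent 1-colour expression arrays, 1 array per pup: 5 wild-type, 3 normoglycaemic KO and 7 hypoglycaemic KO littermates. Per the labels' protocols, livers were snap-frozen, total RNA was extracted with Tri-reagent and checked on a Bioanalyzer, and Cy3-labelled cRNA was made from 200 ng with a low-input one-colour kit. The blood glucose of each pup was taken from the labels. The intensity values of the scanner files (columns gProcessedSignal, gMeanSignal, gMedianSignal and gBGMedianSignal) were made with Agilent Feature Extraction 10.10, per the file headers, which record background subtraction and detrending within the array for gProcessedSignal and no normalization between arrays. The log2 values of the series matrix were made by the authors with limma (version not given), per the submitters' processing notes. The deposited log2 values cover 40048 probes, share their maximum of 19.265 in all columns and correlate at 0.99986 to 0.99999 with the logarithm of gMedianSignal, so that they follow the spot signal without background subtraction. They served as an alternative.

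Levels were computed as the base-2 logarithm of gProcessedSignal minus that of the array's 75th percentile over non-control probes. Each array carried 62976 spots; 3671 control spots were left out, and the 432 probes printed more than once were averaged, leaving 55681 probes. Spots marked by Feature Extraction as non-uniform or as deviating from their replicates (176 to 546 per array) were set to missing, and 0 non-control spots were saturated. A probe was kept if it was well above background on at least 3 of 15 arrays (41139 probes). Probes were named through their accession in the reference table (27235), as a current symbol (3581) or through a unique synonym (565), and otherwise kept the name in the file (24300). The probe with the highest mean stood for each symbol, which left 27542 genes or single-probe transcripts, 16663 of them with a gene symbol. Coordinates are of mm9 (NCBI37), per the file headers.

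One linear model with 3 group means was fitted with limma 3.58.1 (lmFit, eBayes) in R 4.3.3, with 12 residual and 1.83 prior degrees of freedom. Its contrasts were hypoglycaemic KO against wild type, normoglycaemic KO against wild type, hypoglycaemic against normoglycaemic KO, and the equally weighted mean of both KO groups against wild type. A second model added a common slope on blood glucose within groups. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes of a contrast. A fold change is 2 to the power of a difference of group means. Where a group lay at background, the fold is a bound taken with the dimmest signal well above background on each array.

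The 46 gene lists of liver functions, stress and hormone responses and marker genes of other cells were written before the values were seen. They were tested with camera (preset correlation 0.01), camera with the correlation estimated from the data, and fry, each adjusted over the 46 lists. The preset correlation takes members to be nearly independent, which the estimated one does not. The 993 genes with a missing value on some array were left out of these set tests, which used 26549 genes. Members were also adjusted over the list alone. Group values of single measures were compared by exact permutation tests over all splits, and relations across libraries by permutation, with the Pearson r, the Spearman rho and the r without the 2 farthest libraries. The agreement of the KO comparisons was set against 100 simulations without effect in which both shared the wild-type libraries, and against splits of the wild-type libraries. Values far from the rest of their group were found by a Dixon test. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 read the files and drew the figures.

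Genes to be named were set beforehand: per comparison up to 8 called genes in each direction with a proper symbol and well above background on every array of a group; up to 4 passing members of each called list; lists with 3 or more passing members; and 29 genes whatever their result. Some genes that the rule names are not reported here. Per direction 5 slopes were to be named among called genes. As exceptions, chosen after the values were seen, up to 4 members of each called list were named that passed over the list alone, the genes with the smallest p of a slope were named although none passed, and called transcripts outside the rule, Serpina3i, Syt4 and natural killer and T cell genes were named as such. Other probes of a named gene are given where their sign differs.

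The fits were tested on simulated data with the groups of the study and noise independent between genes. Per comparison 200 genes were changed, 67, 67 and 66 of them by 1.5, 2 and 4 fold. Of the genes at each fold, 52.2%, 67.2% and 87.9% were called for hypoglycaemic KO against wild type. The shares were 40.3%, 59.7% and 84.8% for normoglycaemic KO, and 31.3%, 64.2% and 87.9% between the KO groups. In the wrong direction 0 were called, and 5, 7 and 9 unchanged genes were called. Of 46 simulated lists 4 were moved and called, and 0 others were. Members of these lists were uncorrelated, unlike those of most real lists, so that this does not show how camera fares on correlated lists.

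Alternatives fixed beforehand were normexp background correction with quantile normalization, array median scaling, the deposited values, no filter and a filter on all 15 arrays, every probe tested, eBayes with trend and robust, array weights, only the groups compared, slide as a block, each slide alone, replicate number as a block, Ddx3y or erythroid level as a covariate, stricter thresholds, and leaving out each library in turn. Slide row as a block, the exocrine pancreas level as a covariate, and fits without the 3 libraries with the most pancreas transcripts, with and without the library labelled hypoglycaemic KO replicate 2, were chosen after seeing the data. No library was left out of the main results. Targets of the microRNAs by seed match were not analysed here.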

Results

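RNA from the livers of 15 newborn C57BL/6J mice was hybridised to single-colour Agilent expression arrays, 1 array per pup, on postnatal day 1. Wild-type pups (n = 5) were compared with littermates lacking the miR-379/miR-410 cluster on the chromosome from their mother (here KO). The cluster is a large group of microRNA genes in the imprinted Dlk1-Dio3 domain of chromosome 12. The KO pups had been sorted by blood glucose into a group the sample titles call normoglycaemic (n = 3) and a hypoglycaemic group (n = 7). The design text calls the first mildly and the second severely hypoglycaemic. Blood glucose was 58.6 ± 9.56 mg/dl (SD, n = 5) in wild-type, 48 ± 6.93 mg/dl (SD, n = 3) in normoglycaemic KO and 19.9 ± 9.34 mg/dl (SD, n = 7) in hypoglycaemic KO pups. Glucose was lower in hypoglycaemic KO than in wild-type pups (difference −38.7 mg/dl, 2-sided exact permutation test, p = 0.00126, adjusted p = 0.00756 over 18 tests, all 7 values below all 5). Normoglycaemic KO pups did not part from wild type (difference −10.6 mg/dl, exact p = 0.143, adjusted p = 0.368). The difference between the KO groups (−28.1 mg/dl, exact p = 0.00833, adjusted p = 0.03) describes how they were chosen. Since the KO pups were sorted by glucose, the 2 comparisons with wild type also depend on that choice. They do not test the effect of the deletion on glucose. Each array carried 62976 spots. Of the non-control spots 57.9% to 76.2% lay well above background, and the 75th percentile of the processed signal ran from 663 to 912. The arrays lay on 2 slides. Slide 1 held 2 wild-type, 2 normoglycaemic KO and 4 hypoglycaemic KO libraries, and slide 2 held 3, 1 and 3. Against slide 1, slide 2 had a lower 75th percentile (difference −93.2, exact permutation p = 0.000932, adjusted p = 0.00756) and a lower local background (−10.8, exact p = 0.00497, adjusted p = 0.0224). The lower slide row had fewer spots well above background than the upper (difference −8.59 percentage points, exact p = 0.000311, adjusted p = 0.0056). Levels are log2 signal over each array's 75th percentile, and differences are log2 differences of group means. Ddx3y, a Y-linked gene, read 2.09 to 2.55 in wild-type replicate 3, normoglycaemic KO replicates 1 and 3 and the libraries labelled hypoglycaemic KO replicates 1 and 2, and −7.68 to −4.92 in the other 10 libraries. The groups thus differed in their share of males.

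The transcripts of the targeted locus were examined first, in every library. Mirg, the noncoding host transcript that runs through the miR-379/miR-410 cluster, was read by a probe at chromosome 12, 110987569 to 110987628 (mm9). The bounds of the deletion are not given in the sources used here. Its level was 1.29, 1.84, 1.12, 1.62 and 1.43 in wild-type replicates 1 to 5 and −2.56, −2.53 and −2.45 in normoglycaemic KO replicates 1 to 3. In the hypoglycaemic KO group it was −1.93, −1.55, −2.78, −2.32, −2.45 and −0.99 in replicates 1, 3, 4, 5, 6 and 7, and 0.89 in the library labelled hypoglycaemic KO replicate 2. Mirg was thus 15.7-fold lower in normoglycaemic KO than in wild-type livers (exact permutation p = 0.0179, the smallest that 56 splits allow) and 8.28-fold lower in hypoglycaemic KO livers (exact p = 0.00253), or 11-fold lower without the library labelled hypoglycaemic KO replicate 2. A second Mirg probe, at 110979653 to 110979712, gave the same order. It read 0.55 to 1.2 in wild-type, −3.92 to −3.42 in normoglycaemic KO and −4.15 to −1.91 in the other 6 hypoglycaemic KO libraries. It read 0.08 in the library labelled hypoglycaemic KO replicate 2. Over all genes, the limma adjusted p of Mirg was 0.0558 for hypoglycaemic KO (difference −3.05) and 0.141 for normoglycaemic KO (difference −3.97). Every KO library lay below every wild-type library in both.

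Meg3, a maternally expressed noncoding RNA upstream of the cluster, read 5.16 ± 0.23 (SD, n = 7) in hypoglycaemic KO, 5.33 ± 0.21 (SD, n = 3) in normoglycaemic KO and 5.03 ± 0.15 (SD, n = 5) in wild-type livers (exact permutation p = 0.311 and 0.0536). The 2 further Meg3 probes differed from wild type by −0.17 and 0.16 in hypoglycaemic and by 0.8 and 0.47 in normoglycaemic KO livers. Dlk1, a paternally expressed growth regulator of the fetal liver, differed from wild type by 0.28 in hypoglycaemic and 0.27 in normoglycaemic KO livers (limma adjusted p = 0.352 and 0.964). Dio3, which inactivates thyroid hormone, differed by −0.19 and −0.63 (limma adjusted p = 0.836 and 0.964). Rian was not among the tested genes. Of 7 measured members of the Dlk1-Dio3 imprinted domain list, 1 was lower adjusted over the list alone in each KO group. Camera did not call the list (limma's camera, adjusted p = 0.529 and 0.477). The direction of every comparison with hypoglycaemic KO livers below includes the library labelled hypoglycaemic KO replicate 2, whose Mirg level does not match its label.

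**Figure D1:**
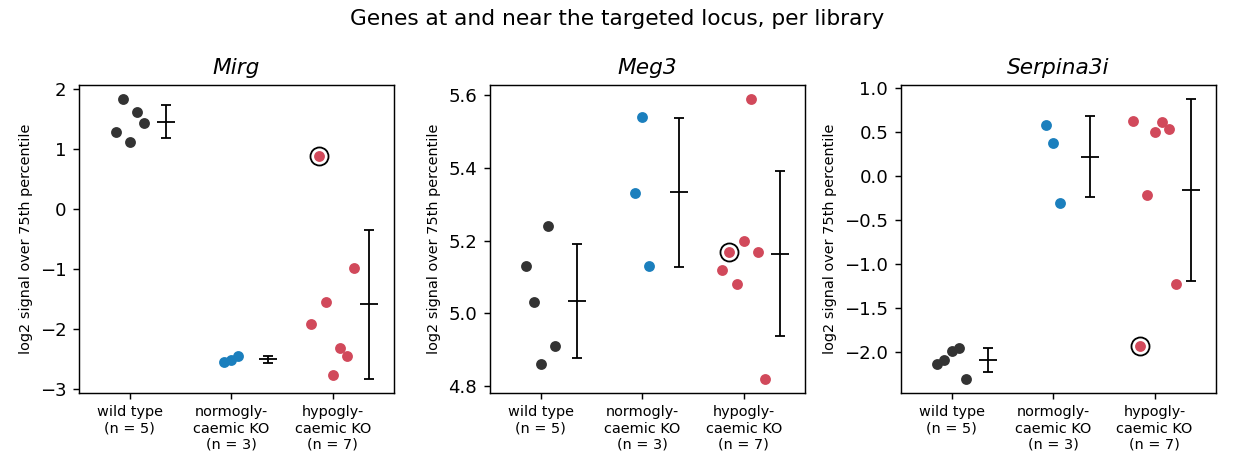
Levels of Mirg, Meg3 and Serpina3i (log2 signal over the array's 75th percentile, vertical axis) per library in the 3 groups, with mean and SD to the right of the points and the library labelled hypoglycaemic KO replicate 2 ringed. Mirg lies at 1.12 or above in wild-type and at −0.99 or below in all KO libraries except the ringed one at 0.89, and Serpina3i at −1.95 or below in wild-type and at −0.3 or above in normoglycaemic KO libraries.

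The comparison of hypoglycaemic KO with wild-type livers asked which hepatic genes change in the pups with the lowest blood glucose. Of 27542 genes or single-probe transcripts, 5 fell and 0 rose in hypoglycaemic KO livers (limma, Benjamini-Hochberg adjusted p under 0.05). Tbx3, a T-box transcription factor needed for growth of the embryonic liver, read 0.68 ± 0.27 (SD, n = 7) against 1.77 ± 0.19 (SD, n = 5). It was 2.13-fold lower, with all 7 libraries below all 5 wild-type libraries (difference −1.09, SE 0.13, limma adjusted p = 0.0164). Gzmb, the granzyme of cytotoxic lymphocytes and natural killer cells, read −0.53 ± 0.31 (SD, n = 7) against 0.59 ± 0.09 (SD, n = 5). This was 2.17-fold lower, again in all 7 libraries (difference −1.12, SE 0.16, limma adjusted p = 0.0477). The other 3 were named after their values were seen. They were the unnamed clone A130072N09Rik (difference −2.001, limma adjusted p = 0.0164), the predicted gene Gm10509 (−0.49, 0.047) and the transcript ENSMUST00000103291 (−0.88, 0.0477). At an unadjusted p under 0.05 lay 5190 genes, 2734 higher and 2456 lower, against 1377 expected on average without any effect. With the libraries regrouped at random, 3 of 100 splits, the real one included, reached this count (highest other 7423). Chance was thus not excluded for it.

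None of the genes of fasting metabolism chosen beforehand passed over all genes. Pdk4, the kinase that holds back pyruvate oxidation, was 2.52-fold higher (difference 1.33, SE 0.3, limma adjusted p = 0.0871, higher than the wild-type mean in all 7). Igf1, the growth factor that the liver makes under growth hormone, was 2.54-fold lower (difference −1.34, SE 0.29, limma adjusted p = 0.0871, lower than the wild-type mean in all 7). A further 4 Igf1 probes lay between −1.52 and −0.29. Differences of the gluconeogenic genes were 0.81 for G6pc, 0.27 for Pck1 and 0.78 for Ppargc1a, and those of the amino acid and urea cycle enzymes Tat and Cps1 were 1.5 and 0.75. Differences of the glycogen genes Gys2 and Pygl were −0.4 and −0.37. Lipid genes gave −0.69 for Srebf1 and −0.25 for Fasn. The fasting hormone Fgf21 gave −1.85, above background in 4 of 7 hypoglycaemic KO libraries, and Cpt1a −0.03, its second probe 0.03. Cyp7a1 (0.32), Saa1 (0.08), Ddit3 (0.34), Igfbp1 (0.23), Mki67 (−0.01), Alb (−0.06), Afp (−0.07), the erythroid gene Alas2 (0.1) and the haemoglobin gene Hbb-bt (−0.01) differed little.

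Genes driven by the hormones of fasting lay higher as a group in hypoglycaemic KO livers. All 28 measured members of the glucagon, cAMP and glucocorticoid response list lay above 0, with a median difference of 0.8. Of these 20 were higher adjusted over the list alone and 0 over all genes (camera adjusted p = 1.04e-11; adjusted p = 0.552 with an estimated correlation). The mean of the list read 4 to 4.4 in 5 hypoglycaemic KO libraries, but 2.78 and 3.04 in replicates 4 and 6, inside the wild-type range of 2.45 to 3.2. Among its members, Pim3 was 2.85-fold higher, Sgk1, a glucocorticoid-induced kinase, 2.63-fold and the transcription factor Cebpd 2.26-fold (limma adjusted p = 0.0871 for each). The growth hormone, IGF and insulin axis list lay lower, with a median of −0.28. Of its 23 members 10 were lower and 1 higher adjusted over the list alone (camera adjusted p = 0.000104; adjusted p = 0.552 with an estimated correlation). It held Igf1, the prolactin receptor Prlr (3.18-fold lower), the thyroid hormone receptor Thrb (1.5-fold lower) and the insulin receptor substrate Irs1 (1.41-fold lower), each at a limma adjusted p of 0.0871. Targets of the amino acid stress factor ATF4 lay higher in the median, with 23 of 29 members above 0 and 6 below. Fgf21, also on this list, went the other way (difference −1.85, limma adjusted p = 0.247). Adjusted over the list alone 4 were higher (integrated stress response (ATF4 targets), median 0.28, camera adjusted p = 0.000572; adjusted p = 0.552 with an estimated correlation). Ddit4, an inhibitor of mTORC1, was 5.96-fold higher (limma adjusted p = 0.0595), Chac1, which degrades glutathione, 2.94-fold, the pseudokinase Trib3 2.77-fold and the leucine sensor Sesn2 1.46-fold. The 12 urea cycle genes had a median of 0.49 with 0 higher adjusted over the list alone and 1 lower (camera adjusted p = 0.0332; adjusted p = 0.62 with an estimated correlation). The immediate-early genes had a median of 0.48 with 6 of 26 higher adjusted over the list alone and 1 lower (camera adjusted p = 0.00553; adjusted p = 0.612 with an estimated correlation). Fos, a subunit of AP-1, was 3.3-fold higher, Ccn2 2.38-fold, Klf6 1.55-fold and Myc 1.54-fold.

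Coagulation, detoxification and some other hepatocyte lists lay lower, while acute-phase proteins had a median of 0 (camera adjusted p = 0.894). Of 32 coagulation and complement genes, 29 lay below 0 and 21 were lower and 1 higher adjusted over the list alone (median −0.41, camera adjusted p = 1.48e-10; adjusted p = 0.552 with an estimated correlation). Among them were Masp1 of the lectin pathway (2.37-fold lower), the clotting factor F7 (1.82-fold), heparin cofactor Serpind1 (1.75-fold) and plasma kallikrein Klkb1 (1.68-fold). Of 43 drug-metabolising enzymes, 23 were lower adjusted over the list alone (median −0.66, camera adjusted p = 7.75e-08; adjusted p = 0.552 with an estimated correlation). Cyp1a2, a caffeine-clearing cytochrome, was 8.79-fold lower, the sulfotransferase gene Sult1c2 5.48-fold, the glutathione transferase gene Gsta2 2.89-fold and the glucuronosyltransferase gene Ugt2b34 2.55-fold. Of 21 bile acid synthesis and transport genes, 8 were lower adjusted over the list alone (median −0.13, camera adjusted p = 0.00808; adjusted p = 0.552 with an estimated correlation). The steroid reductase genes Akr1c6 and Akr1d1 were 12-fold and 2.04-fold lower, the nuclear receptor Nr0b2 2.39-fold and the bile acid conjugating enzyme Baat 2.2-fold. The log2 fold change of Akr1c6, hypoglycaemic KO against wild type, was −3.58, and −2.71 without wild-type replicate 2. Of 22 ER chaperones, 4 were lower and 1 higher adjusted over the list alone (median −0.25, camera adjusted p = 0.000104; adjusted p = 0.552 with an estimated correlation). The stress transcription factor Xbp1 was 1.29-fold lower, Sel1l and Edem1 of ER-associated degradation 1.41-fold and 1.28-fold, and the disulfide isomerase Pdia4 1.41-fold. Of 27 interferon response genes, 25 lay below 0 and 4 were lower adjusted over the list alone (median −0.3, camera adjusted p = 2.1e-05; adjusted p = 0.612 with an estimated correlation). Irf1, a transcription factor of the interferon response, was 1.7-fold lower in all 7 libraries (limma adjusted p = 0.0595). The GTPase gene Iigp1 was 3.79-fold lower, the RNA sensor Ddx58 1.53-fold and Stat2 1.34-fold. Cholesterol biosynthesis had a median of −0.3 with 2 members higher and 2 lower adjusted over the list alone (camera adjusted p = 0.0115; adjusted p = 0.631 with an estimated correlation). That call ended without wild-type replicate 2 (median −0.11), and its members Acat2 and Sc5d were 2.21-fold and 1.47-fold lower. Smaller shifts were called for lipoproteins and lipases (median −0.13; 5 lower and 2 higher adjusted over the list alone), mitochondrial fatty acid oxidation (−0.13), hepatocyte secreted and identity genes (−0.09) and oxidative phosphorylation (−0.08), the last 3 with 0 members passing adjusted over the list alone. Their camera adjusted p were 0.0332, 0.0225, 0.0167 and 0.00622, and their adjusted p with an estimated correlation 0.612, 0.71, 0.612 and 0.88. Among the lipoprotein genes, the lipase Mgll was 1.74-fold lower, and the receptors Scarb1 1.35-fold and Lrp1 1.34-fold, another Lrp1 probe reading 0.32.

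Markers of other cells moved as well. Granulocyte markers had a median of 0.22 (20 of 23 above 0, camera adjusted p = 0.000378; adjusted p = 0.612 with an estimated correlation) and liver endothelial markers 0.15 (17 of 20 above 0, 1 higher adjusted over the list alone, camera adjusted p = 0.00553; adjusted p = 0.612 with an estimated correlation). That 1 was Pecam1, 1.22-fold higher in all 7. Erythroid markers (−0.01), Kupffer cell and macrophage markers (−0.13), B-lineage markers (−0.06), bile duct markers (−0.03) and stellate cell and fibroblast markers (−0.03) were not called. The cell cycle list had a median of −0.15 (35 of 39 below 0, camera adjusted p = 0.00221; adjusted p = 0.792 with an estimated correlation) and ribosomal proteins 0.07 (75 of 78 above 0, camera adjusted p = 9.8e-06; adjusted p = 0.685 with an estimated correlation). Of the 46 lists, camera called 19 in this comparison, 7 higher and 12 lower. With an estimated correlation camera called 0 lists here and 0 in each comparison that follows. Fry, which asks whether a list moves one way as a whole, kept 1 of them, the growth hormone, IGF and insulin axis (limma's fry, adjusted p = 0.0268). Over all genes tested, 0 members of the 46 lists passed limma's threshold in this comparison.

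With slide as a block, limma called 5 genes and camera 17 lists. Within slide 1 these counts were 0 and 17, and within slide 2 they were 0 and 15. The median of the glucagon, cAMP and glucocorticoid response list was 0.82 with the block, 0.95 within slide 1 and 0.74 within slide 2. That of coagulation and complement was −0.42, −0.43 and −0.44, that of drug-metabolising enzymes −0.69, −0.63 and −0.81, and that of the interferon response −0.31, −0.44 and −0.14. The cell cycle list read −0.1, −0.28 and 0.04, so that its direction turned within slide 2, as it did without the 3 libraries richest in pancreas transcripts (0.03). The count of genes moved with single libraries, from 0 without wild-type replicate 3, 4 or 5 to 757 without wild-type replicate 1. It was 138 without the library labelled hypoglycaemic KO replicate 2, and 0 without the 3 libraries richest in pancreas transcripts, an alternative chosen after seeing the data.

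The comparison of normoglycaemic KO with wild-type livers asked what differs in the KO pups with the higher blood glucose. Their glucose was 44 to 56 mg/dl against 50 to 72 mg/dl in wild type. The comparison therefore does not fully part the deletion from a mildly lower glucose. Here 0 of 27542 genes passed (limma, Benjamini-Hochberg), and 1326 lay at an unadjusted p under 0.05 against 1377 by chance. Other settings of the limma analysis called 0 to 5. The median of the fasting-hormone genes lay lower here. Their mean read 2.645 and 2.461 in normoglycaemic KO replicates 1 and 3, inside the wild-type range of 2.448 to 3.203. It read 2.013 in replicate 2, the library with the most pancreas transcripts. Of the members of the glucagon, cAMP and glucocorticoid response list 25 of 28 were below 0, with a median of −0.34 and 0 members passing adjusted over the list alone (camera adjusted p = 7.24e-08; adjusted p = 0.811 with an estimated correlation). Among them G6pc, which releases glucose from glucose 6-phosphate, read 6.05 ± 0.82 (SD, n = 3) against 7.13 ± 0.5 (SD, n = 5), 2.12-fold lower, with all 3 libraries below the wild-type mean (limma adjusted p = 0.964). Pck1, the first committed enzyme of gluconeogenesis, read 6.89 ± 0.63 (SD, n = 3) against 7.7 ± 0.3 (SD, n = 5), 1.75-fold lower, with all 3 below the wild-type mean (limma adjusted p = 0.964). Igfbp1, an insulin-repressed secreted protein, was 1.42-fold lower, Ppargc1a, a coactivator of gluconeogenic genes, 2.22-fold and Tat 2.57-fold (limma adjusted p = 0.964 for each). Pdk4 (−0.5), Cps1 (−0.73), Igf1 (−0.52), Gys2 (−0.19) and Cpt1a (−0.02, second probe 0.14) lay below wild type. Above it lay Fgf21 (0.96), Srebf1 (0.19), Fasn (0.24), Pygl (0.11), Cyp7a1 (0.07), Ddit3 (0.26), Saa1 (0.21) and Mki67 (0.02, second probe −0.02). Alb (0.02), Afp (−0.01), Alas2 (−0.07) and Hbb-bt (−0.02) were close to wild type.

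Other metabolic groups lay lower with it. Amino acid catabolism had a median of −0.22 (31 of 36 below 0, camera adjusted p = 2.42e-07; adjusted p = 0.764 with an estimated correlation), bile acid synthesis and transport −0.24 (16 of 21, camera adjusted p = 0.000125; adjusted p = 0.665 with an estimated correlation) and ER chaperones −0.22 (18 of 22, camera adjusted p = 0.000122; adjusted p = 0.764 with an estimated correlation). The urea cycle had a median of −0.33 (10 of 12, camera adjusted p = 0.0196; adjusted p = 0.828 with an estimated correlation) and coagulation and complement −0.13 (29 of 32, camera adjusted p = 0.00123; adjusted p = 0.828 with an estimated correlation). The coagulation and complement call ended without wild-type replicate 2. Oxidative phosphorylation had a median of −0.09 (82 of 94 below 0, camera adjusted p = 4.31e-06; adjusted p = 0.858 with an estimated correlation), which was 0 within slide 1. Smaller shifts were called for the TCA cycle (−0.11), the growth hormone, IGF and insulin axis (−0.11), acute-phase proteins (−0.1), hepatocyte secreted and identity genes (−0.09), gluconeogenesis (−0.09) and ribosomal proteins (−0.03). Their camera adjusted p were 0.00613, 0.00613, 0.0284, 0.00594, 0.0387 and 0.00813, and their adjusted p with an estimated correlation 0.828, 0.764, 0.858, 0.811, 0.828 and 0.869. The cell cycle list lay higher, with a median of 0.13 (37 of 39 above 0, camera adjusted p = 0.0126; adjusted p = 0.869 with an estimated correlation). Beside these, 22 of 22 exocrine pancreas markers lay above 0, with a median of 1.25 (camera adjusted p = 0.0199; adjusted p = 0.869 with an estimated correlation). Megakaryocyte and platelet markers had a median of −0.14 (camera adjusted p = 0.00157; adjusted p = 0.811 with an estimated correlation). Without normoglycaemic KO replicate 2 the median of the exocrine pancreas markers turned to −1.43. It was 0.68 with slide as a block, 1.21 within slide 1 and −0.56 within slide 2. Camera called 16 of the 46 lists, 2 higher and 14 lower, of which fry kept 0. Of all members 0 passed adjusted over the list alone, save 1 of the Dlk1-Dio3 imprinted domain.

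With slide as a block limma called 0 genes and camera 16 lists. Within slide 1 these counts were 0 and 9. Within slide 2, where 1 normoglycaemic KO library stood alone and was taken to vary like the others, they were 3 and 20. The median of the glucagon, cAMP and glucocorticoid response list was −0.36 with the block, −0.39 within slide 1 and −0.39 within slide 2, and that of amino acid catabolism −0.23, −0.23 and −0.24. Normoglycaemic KO replicate 2 weighed most on the lists, of which 10 were called without it.

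**Figure D2:**
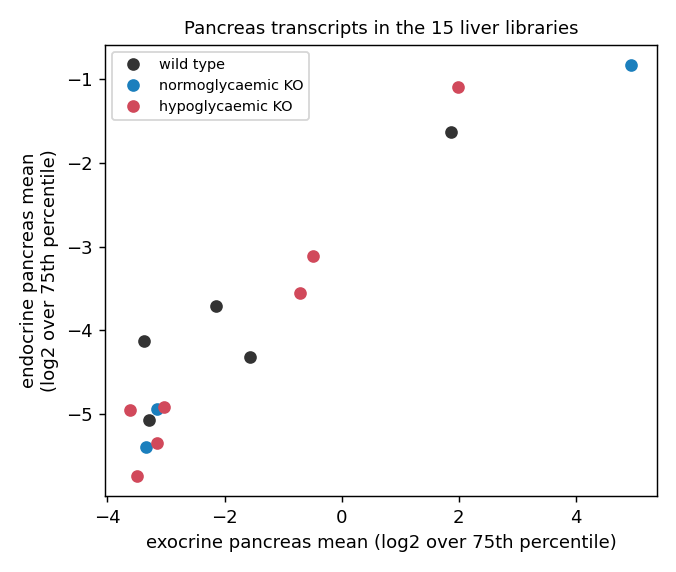
Mean level of the exocrine pancreas markers (horizontal axis) and of endocrine pancreas genes (vertical axis), both in log2 signal over the array's 75th percentile, 1 point per liver library coloured by group. The 3 libraries at the upper right are normoglycaemic KO replicate 2 (4.95 on the horizontal axis), hypoglycaemic KO replicate 3 (1.99) and wild-type replicate 2 (1.87), 1 from each group.

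The comparison of hypoglycaemic with normoglycaemic KO livers, which carry the same genotype label and differ in blood glucose, is also the test of the difference between the KO effects. Here 15 genes passed, 6 higher and 9 lower in hypoglycaemic KO livers (limma, Benjamini-Hochberg), and 5352 lay at an unadjusted p under 0.05 against 1377 by chance. Depp1, a FOXO target induced by fasting, was 3.69-fold higher, at 5.57 ± 0.46 (SD, n = 7) against 3.69 ± 0.55 (SD, n = 3) (limma adjusted p = 0.0442). Ip6k2, an inositol hexakisphosphate kinase, was 2.38-fold higher (limma adjusted p = 0.0483). Angptl8, a secreted inhibitor of lipoprotein lipase that insulin and feeding induce, was 5.67-fold lower, at 2.42 ± 0.58 (SD, n = 7) against 4.92 ± 0.3 (SD, n = 3) (limma adjusted p = 0.0483). Ppp1r3c, a glycogen-targeting subunit of protein phosphatase 1, was 5.59-fold lower, at −1.36 ± 0.67 (SD, n = 7) against 1.12 ± 0.18 (SD, n = 3) (limma adjusted p = 0.0442). In each of these genes all 7 hypoglycaemic KO libraries lay on one side of all 3 normoglycaemic KO libraries. The differences were 1.88 (SE 0.29), 1.25 (SE 0.2), −2.5 (SE 0.41) and −2.48 (SE 0.37).

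Mapk15, an atypical MAP kinase, was 1.74-fold higher (difference 0.8, SE 0.12, limma adjusted p = 0.0442, higher in all 7). Agap2, a GTPase-activating protein, was 1.63-fold lower (difference −0.71, SE 0.11, limma adjusted p = 0.0458, in all 7). Prl7b1, a gene of the prolactin family, was at least 2.61-fold lower. Of the hypoglycaemic KO libraries 0 of 7 were well above background, so this bound sets the normoglycaemic KO mean against the dimmest signal well above background on each array (limma adjusted p = 0.0458, measured means −7.53 and −3.87). Named after its values were seen, Syt4, a synaptotagmin of secretory vesicles, was higher by a difference of 2.55 (limma adjusted p = 0.0329), and A130072N09Rik was lower by a difference of −2.06 (limma adjusted p = 0.0329). The difference from wild type of the same genes was not past the threshold in either KO group, save A130072N09Rik in hypoglycaemic KO. In Agap2 the hypoglycaemic KO libraries (−1.6 to −1.2) overlapped wild type (−1.49 to −1.09), and the normoglycaemic KO libraries lay apart (−0.81 to −0.5). The same held for Prl7b1 (−8.13 to −6.96, −8.15 to −4.83 and −4.56 to −3.03) and Mapk15 (−4.15 to −3.63, −4.22 to −4.03 and −4.99 to −4.46), in the same order of groups.

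**Figure D3:**
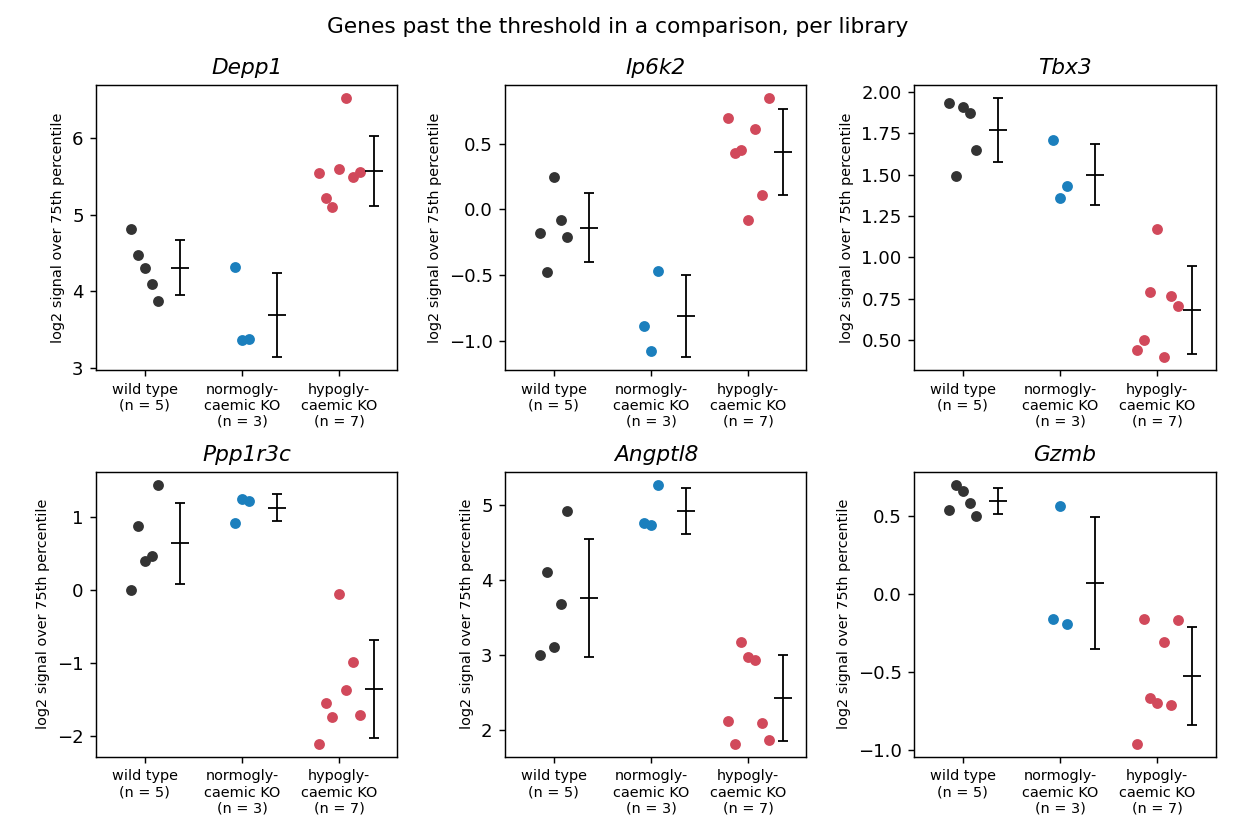
Levels (log2 signal over the array's 75th percentile, vertical axis) of 6 genes that passed in a comparison, 1 point per library in the 3 groups, with mean and SD to the right of the points. Depp1 and Ip6k2 are higher and Ppp1r3c and Angptl8 lower in all 7 hypoglycaemic KO than in all 3 normoglycaemic KO libraries, and Tbx3 and Gzmb are lower in all 7 hypoglycaemic KO than in all 5 wild-type libraries.

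Among the lists called between the KO groups, the fasting-hormone genes stood farthest apart. All 28 members of the glucagon, cAMP and glucocorticoid response list lay higher in hypoglycaemic KO livers, with a median of 1.43. Adjusted over the list alone 24 were higher, against 0 over all genes (camera adjusted p = 1.81e-20; adjusted p = 0.687 with an estimated correlation). Fry, of limma, kept this call (adjusted p = 0.0464) and no other of the comparison. G6pc read 7.95 ± 0.4 (SD, n = 7) against 6.05 ± 0.82 (SD, n = 3), or 3.72-fold higher. Pdk4 was 3.57-fold higher and the glucocorticoid-induced factor Klf9 2.75-fold (limma adjusted p = 0.064 for each), with all 7 libraries above all 3. Pck1 was 2.11-fold higher (limma adjusted p = 0.0866), Ppargc1a 3.81-fold (0.0968), Tat 7.26-fold (0.0876), the phosphatase gene Dusp1 2.34-fold (0.141) and Igfbp1 1.66-fold (0.0663). The urea cycle had a median of 0.75 with 7 of 12 members higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00113; adjusted p = 0.687 with an estimated correlation). Cps1, its entry enzyme, was 2.8-fold higher and Asl, the argininosuccinate lyase gene, 2.4-fold, the ornithine carrier Slc25a15 2.28-fold and glutamine synthetase Glul 1.46-fold. Amino acid catabolism had a median of 0.38 with 12 of 36 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.00131; adjusted p = 0.687 with an estimated correlation). The serine dehydratase gene Sds was 8.79-fold higher and Mat1a, which makes S-adenosylmethionine, 2.31-fold, and the lysine-degrading Aass 2.68-fold.

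The lists of cholesterol biosynthesis, drug-metabolising enzymes, interferon response and cell cycle had medians below 0 in hypoglycaemic against normoglycaemic KO livers. Of 26 cholesterol biosynthesis genes, 12 were lower and 2 higher adjusted over the list alone (median −0.56, camera adjusted p = 0.00113; adjusted p = 0.687 with an estimated correlation). Cyp51 was 3.19-fold lower and squalene synthase Fdft1 1.87-fold. Of 27 interferon response genes, 26 lay below 0 and 5 were lower adjusted over the list alone (median −0.51, camera adjusted p = 1.52e-06; adjusted p = 0.687 with an estimated correlation). Irf1 was 1.84-fold lower in all 7 (limma adjusted p = 0.064), Stat2 1.56-fold, Ddx58 1.59-fold and Psmb9 1.58-fold. The cell cycle list had a median of −0.35, with 37 of 39 below 0 and 0 passing adjusted over the list alone (camera adjusted p = 1.07e-05; adjusted p = 0.687 with an estimated correlation). Of 43 drug-metabolising enzymes, 7 were lower and 2 higher adjusted over the list alone (median −0.47, camera adjusted p = 0.000686; adjusted p = 0.687 with an estimated correlation), with Cyp1a2 5.37-fold lower, Sult1c2 5.33-fold, Ugt2b34 3.05-fold and Gsta2 2.75-fold. Coagulation and complement had a median of −0.3 with 0 passing (camera adjusted p = 0.00192; adjusted p = 0.687 with an estimated correlation). Fgf21 (−2.81), Igf1 (−0.82), Srebf1 (−0.87), Fasn (−0.5), Pygl (−0.48) and Gys2 (−0.21) had negative differences, none past the threshold. The size of the Fgf21 difference is uncertain, since Fgf21 was well above background in 4 of 7 hypoglycaemic KO libraries. Mirg (0.92), Dio3 (0.44), Cyp7a1 (0.25), Alas2 (0.18), Ddit3 (0.08), Hbb-bt (0.02), Dlk1 (0.01), Cpt1a (−0.01), Mki67 (−0.03), Afp (−0.05), Alb (−0.08), Saa1 (−0.13) and Meg3 (−0.17) did not pass either. Beside these groups, granulocyte markers had a median of 0.25 (22 of 23 above 0, camera adjusted p = 3.4e-05; adjusted p = 0.687 with an estimated correlation). Liver endothelial markers had 0.16 (camera adjusted p = 0.0138; adjusted p = 0.687 with an estimated correlation) and exocrine pancreas markers −1.27 (22 of 22 below 0, camera adjusted p = 0.0679), which turned to 1.29 without normoglycaemic KO replicate 2. Also called were ribosomal proteins (median 0.11), immediate-early genes (0.31), megakaryocyte and platelet markers (0.11) and mitochondrial fatty acid oxidation (−0.13). Their camera adjusted p were 7.69e-09, 0.0201, 0.0201 and 0.0462, and their adjusted p with an estimated correlation 0.687, 0.687, 0.687 and 0.73. Adjusted over the list alone 6 immediate-early genes were higher and 1 lower. Ccn2 was 2.71-fold higher, Fosl2 1.79-fold and Klf6 1.71-fold. Camera called 14 of the 46 lists, 8 higher and 6 lower.

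With slide as a block limma called 0 genes and camera 13 lists, within slide 1 0 genes and 10 lists, and within slide 2 3 genes and 19 lists. The log2 fold change of Depp1, hypoglycaemic KO against normoglycaemic KO, was 1.89 with the block (limma adjusted p = 0.0639), 1.52 within slide 1 and 2.48 within slide 2. The log2 fold change of Ppp1r3c, hypoglycaemic KO against normoglycaemic KO, was −2.5 with the block (limma adjusted p = 0.0577), −2.44 within slide 1 and −2.56 within slide 2. The median of the glucagon, cAMP and glucocorticoid response list was 1.43 with the block, 1.3 within slide 1 and 1.35 within slide 2. That of the urea cycle was 0.74, 0.87 and 0.71, that of cholesterol biosynthesis −0.53, −0.54 and −0.46, that of the interferon response −0.52, −0.58 and −0.49, and that of the cell cycle −0.36, −0.44 and −0.17. Without the library labelled hypoglycaemic KO replicate 2 limma called 0 genes and the median of the glucagon, cAMP and glucocorticoid response list was 1.34. Without hypoglycaemic KO replicate 4, the library of the group with the highest blood glucose, limma called 988 genes.

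**Figure D4:**
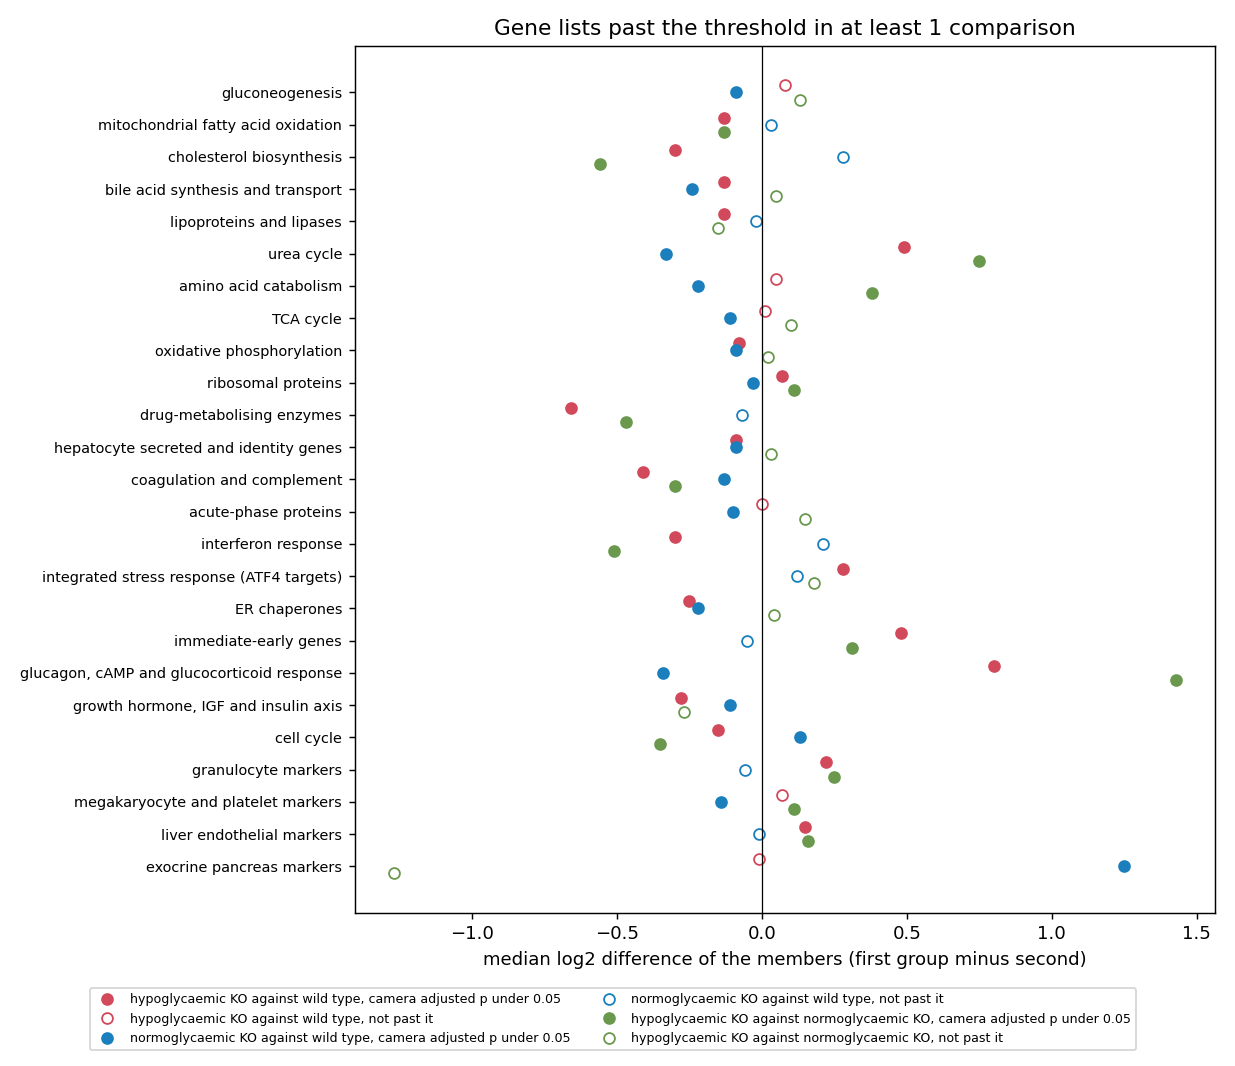
Median log2 difference of the members (first group minus second, horizontal axis) of each gene list that camera called in at least 1 comparison, in hypoglycaemic KO against wild type (red), normoglycaemic KO against wild type (blue) and hypoglycaemic against normoglycaemic KO (green). Filled points have a camera adjusted p under 0.05 and open points do not; the glucagon, cAMP and glucocorticoid response list lies at 0.8, −0.34 and 1.43.

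The comparison of both KO groups, weighted equally, with wild type asked what the deletion does whatever the glucose. Here 2 transcripts fell in KO against wild-type livers and 0 rose (limma, Benjamini-Hochberg), with 1847 at an unadjusted p under 0.05. They were Mirg (difference −3.51, limma adjusted p = 0.0491, lower in all 10 KO libraries) and a noncoding RNA probe whose name in the files places it on the forward strand of chromosome 12 across the Mirg probe (difference −1.48, limma adjusted p = 0.0491). With slide as a block 0 were called, and within each slide 0. Without the library labelled hypoglycaemic KO replicate 2 the count was 17. Serpina3i, a serine protease inhibitor gene at chromosome 12, 105504738 to 105504797 (mm9), 5.5 Mb from Mirg, was named after its values were seen. It read −2.3 to −1.95 in wild-type libraries, −0.3 to 0.58 in normoglycaemic KO libraries (4.95-fold higher, exact permutation p = 0.0179) and −1.93 to 0.62 in hypoglycaemic KO libraries (3.82-fold higher, exact p = 0.00379), where the lowest value was that of the library labelled hypoglycaemic KO replicate 2. Its limma adjusted p for both groups together was 0.339.

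The effects of the KO groups against wild type were compared across genes, which are not independent replicates and share the wild-type libraries. Their log2 differences correlated at r = 0.203, against 0.466 (0.435 to 0.512) for simulated groups with no effect sharing the same 5 wild-type libraries. With the residuals of whole arrays reshuffled instead, r averaged 0.467 (0.09 to 0.79), a range that holds 0.203. Their covariance was 0.026 against 0.041 simulated, a difference of −0.015. With the wild-type libraries split so that each KO group had its own, r averaged −0.095 (−0.314 to 0.147 over 20 splits). The sign was the same in 54.9% of genes, against 65.5% simulated. Limma called 0 genes in both. At an unadjusted p under 0.05, 147 genes were higher in both and 133 lower in both. Independent lists would share 86.2 and 40.8, numbers that take no account of the shared wild-type libraries. The medians of the fasting-hormone genes lay on opposite sides of wild type in the KO groups, as did those of the urea cycle (0.49 and −0.33) and the cell cycle (−0.15 and 0.13). The medians of the interferon response (−0.3 and 0.21) and cholesterol biosynthesis (−0.3 and 0.28) did as well, but camera did not call these lists in normoglycaemic KO livers (adjusted p = 0.0967 and 0.0555). Other lists were called lower by camera in both KO groups. They were coagulation and complement (−0.41 and −0.13), ER chaperones (−0.25 and −0.22) and the growth hormone, IGF and insulin axis (−0.28 and −0.11). So were bile acid synthesis and transport (−0.13 and −0.24), hepatocyte secreted and identity genes (−0.09 and −0.09) and oxidative phosphorylation (−0.08 and −0.09).

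Within groups, the relation of each gene to the pup's own blood glucose was tested as 1 common slope. Limma called 0 genes, with 4984 at an unadjusted p under 0.05 against 1377 by chance and a smallest adjusted p of 0.0551. Over the 7 hypoglycaemic KO libraries alone it called 0, with 3685 at an unadjusted p under 0.05. The genes with the smallest p were named after their values were seen. Slopes above 0 were those of the cholesterol synthesis enzyme Sqle (0.7 log2 per 10 mg/dl, SE 0.11, limma adjusted p = 0.0561), Baat (0.53, SE 0.08, 0.0551), the splicing gene Snrpd1 (0.24) and the DNA replication genes Rfc3 (0.43) and Pold2 (0.31). Slopes below 0 were those of the keratin Krt23 (−0.54, SE 0.08, limma adjusted p = 0.0551), the nuclear receptor Rora (−0.32), the ubiquitin ligase genes Rnf125 (−0.51) and Rmnd5a (−0.28), and Mlycd, which relieves the block on fatty acid oxidation (−0.24). Of 46 list means, that of cholesterol biosynthesis correlated with glucose at r = 0.78 over the 15 libraries, each taken relative to its group (permutation p = 0.0015, adjusted p = 0.0529, rho 0.64; r = 0.59 without the 2 libraries farthest in glucose). That of the glucagon, cAMP and glucocorticoid response list correlated at r = −0.75 (permutation p = 0.0023, adjusted p = 0.0529, rho −0.55; r = −0.61 without the 2 farthest). The urea cycle followed at r = −0.75 (permutation p = 0.0039, adjusted p = 0.0598, rho −0.7; r = −0.62 without the 2 farthest), megakaryocyte and platelet markers at r = −0.73 (permutation p = 0.0052, adjusted p = 0.0598, rho −0.72; r = −0.74 without the 2 farthest) and the cell cycle at r = 0.72 (permutation p = 0.0066, adjusted p = 0.0607, rho 0.77; r = 0.61 without the 2 farthest). None of the 46 passed the threshold after adjustment, and over the 7 hypoglycaemic KO libraries alone the fasting-hormone list gave r = −0.71 (exact permutation p = 0.0812, adjusted p = 0.654, rho −0.32).

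**Figure D5:**
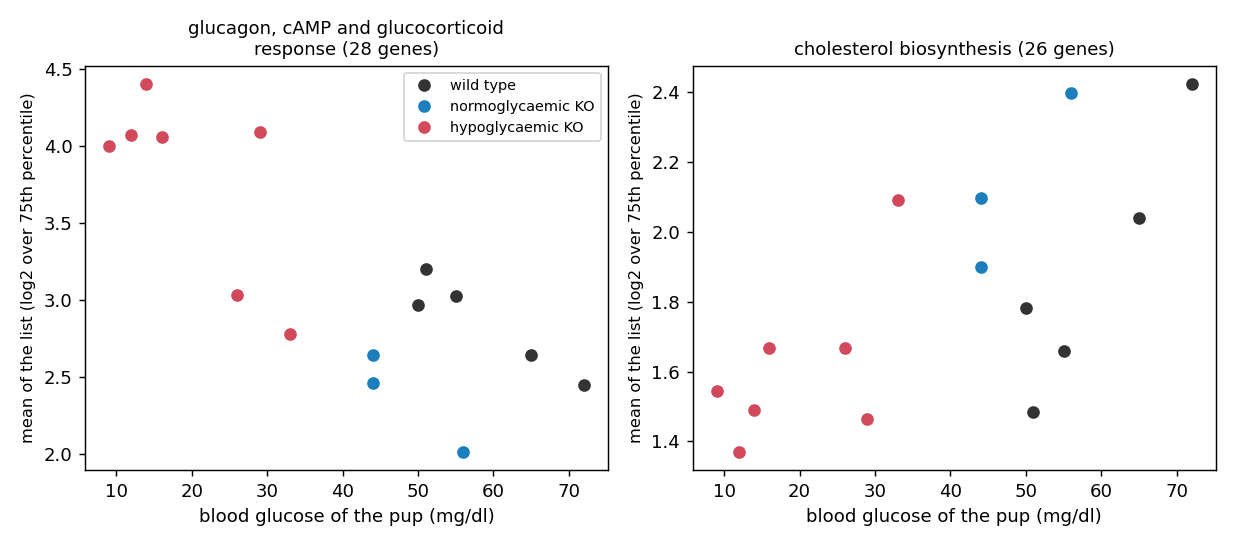
Mean level of the glucagon, cAMP and glucocorticoid response list (left) and of cholesterol biosynthesis (right), in log2 signal over the array's 75th percentile, against the pup's blood glucose in mg/dl, 1 point per library coloured by group. Taken relative to their groups, the 15 libraries give r = −0.75 on the left and r = 0.78 on the right, neither past the threshold after adjustment over 46 lists.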

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

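The tests of a wrong label, a swap and a mixture for Mirg, of the study groups for the pancreas transcripts, and of blood glucose for the fasting-hormone genes were chosen after seeing the results, as were the fits without the libraries rich in pancreas transcripts. Of 284 groups of values examined, 24 held a value far from the rest, where chance gives about 1 in 20, or 14.2.

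Mirg lay near the wild-type level (0.89) in the library labelled hypoglycaemic KO replicate 2, against −2.78 to −0.99 in the other 6. RNA of 1 of the 5 wild-type livers mixed in would have to make up at least 59.2% of the RNA and bring Xist to −3.35 or above. Xist was −7.01, a shortfall of 3.65, or of at least 1.45 since Xist was not well above background there. This argued against RNA of wild-type replicates 1, 2, 4 and 5 (Xist 1.55 to 1.9). It cannot decide for wild-type replicate 3, the source of the bound (Xist −2.59), which had the Ddx3y level of a male (2.25), as had the questioned library (2.55). The Xist of wild-type replicate 3 lay above that of the other libraries with such a Ddx3y level (−7.84 to −4.96), so that the test there rests on 1 unusual reading. A swap with a wild-type library of the series was argued against, since 0 wild-type libraries had Mirg at the KO level. A single wrong genotype label fits Mirg and its surroundings. At 7 of 10 probes within 50 kb that part the genotypes the library lay within 2 SD of the wild-type mean, against 0 to 2 in the other hypoglycaemic KO libraries. Other measures went both ways. Outside the wild-type range, on the side of the hypoglycaemic KO group, lay glucose (16 mg/dl, wild type 50 to 72) and the fasting-hormone mean (4.06, 2.45 to 3.2). So did Tbx3 (0.5, 1.49 to 1.93) and Gzmb (−0.16, 0.5 to 0.7), both called with this library included, and the natural killer and T cell mean (−1.52, −1.34 to −1.07). Inside the wild-type range, and above the other 6 hypoglycaemic KO libraries, lay the mean of coagulation and complement (4.62, wild type 4.49 to 5.01). So did bile acid synthesis and transport (2.28, 2.06 to 2.46) and the growth hormone, IGF and insulin axis (2.45, 2.35 to 2.67). Expression from the paternal copy is open and was not tested: the mean of the immunoglobulin stretch of chromosome 12 in this library (−3.63) lay above every wild-type library (−4.2 to −3.83), but hypoglycaemic KO libraries reached down to −4, and its Serpina3i (−1.93) lay beside the wild-type libraries (−2.3 to −1.95).

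Exocrine pancreas transcripts were high in normoglycaemic KO replicate 2 (4.95), hypoglycaemic KO replicate 3 (1.99) and wild-type replicate 2 (1.87), against −3.61 to −0.49 elsewhere. Pancreatic tissue in the liver sample fits: the mean of 6 endocrine genes followed the exocrine mean over the 15 libraries (r = 0.95, permutation p = 1e-05, rho 0.86; r = 0.93 without the 2 farthest). Gut tissue was argued against (r = 0.07, permutation p = 0.81, rho 0.32; r = 0.25 without the 2 farthest). The study groups as their cause were argued against, since the 3 libraries lay in 3 groups.

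The fasting-hormone genes stood apart between the KO groups, by a median of 1.43. Slide was argued against, since the median with slide as a block was 1.43, and pancreatic tissue was argued against, since it was 1.23 without the 3 libraries. Blood glucose itself could be the cause and the test cannot tell: inside the 7 hypoglycaemic KO libraries the list followed glucose at r = −0.71 (exact permutation p = 0.0812, rho −0.32; r = −0.83 without the 2 farthest).

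When the libraries were regrouped at random, 3 of 100 splits, the real one included, called as many genes between hypoglycaemic KO and wild type as the real 5. That share lay under the limit set beforehand, but the highest other split called 2496, so that chance was not excluded. That split exchanged wild-type replicate 1 and hypoglycaemic KO replicate 4, whose Mirg levels (1.29 and −2.78) match their labels. Wild-type replicate 1 had the highest fasting-hormone mean of its group (3.2) and hypoglycaemic KO replicate 4 the lowest of its group (2.78). The pup of hypoglycaemic KO replicate 4 also had the highest glucose of its group (33 mg/dl). Whether this accounts for the count of that split was not tested. The unadjusted count of that comparison gave 3 of 100 as well (real 5190, highest other 7423), which does not exclude chance either. For normoglycaemic KO against wild type the called genes cannot decide, since with a real count of 0 every split reaches it (56 of 56, highest other 4). For its unadjusted genes chance could not be excluded (17 of 56, real 1326, highest other 3414). Between the KO groups 3 of 100 splits called as many genes as the real 15 (highest other 20), so that chance was not excluded for called genes. It was argued against for unadjusted genes, where only the real split reached its count (1 of 100, real 5352, highest other 4705). For both KO groups against wild type 3 of 100 splits called as many genes as the real 2 (highest other 294). In unadjusted genes 26 of 100 reached the real 1847 (highest other 6415). Chance was excluded for neither count.

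In wild-type replicate 2, Sesn2 was 1.16 (others 1.59 to 1.73), G6pc 6.26 (7.16 to 7.45), Fasn −1.53 (−2.56 to −2.34), Gsta2 1.08 (−0.3 to 0.03) and Prlr 1.17 (−0.28 to 0.09). Its list means were 4.57 for gluconeogenesis (5.09 to 5.22), 4.72 for the TCA cycle (5.01 to 5.12) and 7.31 for ribosomal proteins (7.44 to 7.49). In wild-type replicate 1, Pdia4 was 1.02 (1.47 to 1.65) and the mean of gut markers −0.42 (−1.26 to −1.02). The mean of mitochondrial fatty acid oxidation was 5.59 in wild-type replicate 5 (5.31 to 5.34) and that of sex-linked genes −0.23 in wild-type replicate 3 (−4.52 to −3.59), which had the Ddx3y level of a male. In hypoglycaemic KO replicate 5, Depp1 was 6.52 (5.1 to 5.59), Klf6 3.96 (2.81 to 3.28) and Myc 2.94 (1.77 to 2.05), and the list means 1.36 for the hypoxia response (0.24 to 0.64), 0.61 for immediate-early genes (−0.48 to −0.04) and 0.5 for the circadian clock (−0.22 to 0.06). In the library labelled hypoglycaemic KO replicate 2, Nr0b2 was 0.77 (−2.01 to −0.81), Prlr 0.41 (−2.3 to −1.22) and the mean of adrenal and kidney markers −2.3 (−3.54 to −3.26). Dio3 was −2.5 (−4.38 to −3.75) and the cholesterol biosynthesis mean 2.09 (1.37 to 1.67) in hypoglycaemic KO replicate 4, and the acute-phase mean 4.38 (3.45 to 3.78) in hypoglycaemic KO replicate 7.

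The effect in hypoglycaemic KO minus that in normoglycaemic KO passed the threshold of limma for Depp1 (1.88), Ip6k2 (1.25), Mapk15 (0.8), Agap2 (−0.71), Ppp1r3c (−2.48), Angptl8 (−2.5) and Prl7b1 (−3.66). Prl7b1 was well above background in 0 of 7 hypoglycaemic KO libraries, so that only a bound of at least 2.61-fold lower holds for it.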

How the results depend on the processing

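Alternatives using slide row, pancreas transcripts or the target check were chosen after seeing the data. The cause of these changes was not tested. "Only the groups compared" gives no value for both KO groups against wild type, which uses all groups. Of 5174 values of named genes under an alternative, 4781 kept their call and size, 188 were weaker, 202 stronger, 3 moved and 0 reversed. The sign changed in 127 with neither value past the threshold, and in 128 of 157 pairs of gene and comparison it never changed. Of the named genes called, Tbx3 passed under 24 of 33 alternatives, Gzmb under 16, Mapk15 under 12, Angptl8, Depp1 and Ppp1r3c under 10 each, Agap2 under 9, Ip6k2 under 8 and Prl7b1 under 9 of 32. The comparisons are named A (hypoglycaemic KO against wild type, 5 genes called), B (normoglycaemic KO against wild type, 0), C (hypoglycaemic against normoglycaemic KO, 15), D (both KO groups against wild type, 2) and E (slope on glucose, 0). Counts of genes called are given where they moved by more than 1.5 times. Smaller moves are left out.

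Genes called in A, B, C and E were 73, 1, 138 and 473 with normexp and quantile normalization, 50, 2, 31 and 292 with the deposited values, 77, 1, 166 and 537 with a filter on all 15 arrays, and 90, 1, 183 and 506 with trend and robust. Array median scaling gave 25, 1 and 5 in A, B and C. Array weights gave 736, 5, 1981 and 4 in A, B, C and D. The genes of A were 0 higher and 5 lower, against 28 and 62 with trend and robust, 337 and 399 with array weights and 396 and 361 without wild-type replicate 1. No filter gave 2, 0 and 0 in A, C and D. Testing every probe gave 3 in B and 6 in C, and only the groups compared 3, 3 and 2 in A, B and C. Ddx3y as a covariate gave 2 in A and 213 in C. The erythroid covariate gave 22, 2, 0 and 1 in A, C, D and E. An adjusted p under 0.01 gave 0 in A, C and D. Slide as a block gave 0 in C and D. Within slide 1, A, C and D gave 0 and E gave 1. Within slide 2, A, B, C and D gave 0, 3, 3 and 0. Slide row as a block gave 15 in A and 0 in D. The pancreas covariate gave 17, 8 and 0 in A, C and D. Without the 3 libraries with the most pancreas transcripts these were 0, 0 and 1, and without those and the library labelled hypoglycaemic KO replicate 2 they were 19, 0 and 7.

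Of gene lists called by camera in A, B and C (19, 16 and 14), 0, 0 and 0 held with an estimated correlation and 1, 0 and 1 with fry. Within slide 1, 9 were called for normoglycaemic KO. The correlation of the KO effects (0.203) was 0.04 with normexp and quantile normalization, 0.034 with the filter on all 15 arrays and −0.095 with the wild-type arrays split.

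With replicate number as a block, genes called were 0, 1, 0, 1 and 1 in A to E. The labels do not say that a number marks a shared litter, batch or day, and not every same-number pair correlated above 0.1: r of deviations from the group means was −0.175 to 0.316 in 11 same-number pairs, 6 of them above 0.1, and −0.284 to 0.223 in 60 other pairs. Of 13 libraries with a partner, 6 correlated best with their own number, a hint from the data and not from the labels. Within each group the numbers follow slide, row and position on the slide. Array placement was thus not told apart from any other meaning of the number. With replicate number as a block camera called 18, 15 and 12 lists in A, B and C, and none of the 9 named genes called without it passed.

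Leaving out each library in turn gave 0 to 757 genes for hypoglycaemic KO against wild type: 757 without wild-type replicate 1, 1 without wild-type replicate 2, 0 without wild-type replicate 3, 4 or 5, 2 without normoglycaemic KO replicate 1, 3 without normoglycaemic KO replicate 2, 0 without hypoglycaemic KO replicate 1 or 7, 138 without the library labelled hypoglycaemic KO replicate 2, 2 without hypoglycaemic KO replicate 3, 5 or 6, and 519 without hypoglycaemic KO replicate 4. Normoglycaemic KO against wild type gave 0 to 2: 1 without wild-type replicate 5 and 2 without the library labelled hypoglycaemic KO replicate 2. Hypoglycaemic against normoglycaemic KO gave 0 to 988: 4 without wild-type replicate 1, 3 or 4, 308 without wild-type replicate 2, 0 without normoglycaemic KO replicate 1 or 3, 1 without normoglycaemic KO replicate 2, 0 without hypoglycaemic KO replicate 1, 3, 5 or 7 or the library labelled hypoglycaemic KO replicate 2, 988 without hypoglycaemic KO replicate 4 and 6 without hypoglycaemic KO replicate 6. Both KO groups gave 0 to 17, 17 without the library labelled hypoglycaemic KO replicate 2 and 0 without any other. The slope gave 0 to 991: 48, 12 and 991 without hypoglycaemic KO replicate 1, 3 and 7 and 1 without the library labelled hypoglycaemic KO replicate 2. Lists called were 16 to 21, 10 to 18 (10 without normoglycaemic KO replicate 2) and 10 to 18. The correlation of the KO effects was 0.097 to 0.367, the last without wild-type replicate 1. Glucose differences were −40.9 to −35.4, −14.6 to −7.25 and −30.3 to −24.1 mg/dl. The 75th percentile of the signal in the lower minus the upper slide row was −63.7 with all libraries (exact permutation p = 0.0608, adjusted p = 0.182) and −75.6 to −44.4 with 1 left out, past the threshold without wild-type replicate 2 (−72.1), wild-type replicate 3 (−73.4), the library labelled hypoglycaemic KO replicate 2 (−71.9), hypoglycaemic KO replicate 5 (−73.9) or hypoglycaemic KO replicate 6 (−75.6).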

Other observations

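The natural killer and T cell list was written after 3 of its genes were seen, and the loss of blood-derived cells, the glucose-adjusted fit and the count outside the immunoglobulin stretch were tests chosen after seeing the results. Genes of natural killer and T cells were lower in hypoglycaemic KO than in wild-type livers. Of 21 such genes 19 lay below 0 (median −0.77), 11 were lower adjusted over the list alone and 1, Gzmb, over all genes, and their mean differed by −0.78 (exact permutation p = 0.00126); without the 3 seen first it differed by −0.67 (18 genes, exact p = 0.00505). The T cell receptor chain Cd3g was 2.44-fold lower, Gzma 2.31-fold and the receptor Klrd1 1.98-fold, while Prf1 (0.06), Cd3e (−0.06), Cd2 (0.13) and Thy1 (−0.02) were not. The chemokine Xcl1 and Ifng were well above background in 5 of 5 wild-type and 1 of 7 hypoglycaemic KO libraries each, so that no fold is given. In normoglycaemic KO livers the median was −0.2 (16 below 0, exact p = 0.0179, the smallest that 56 splits allow). For a loss of blood-derived cells as a whole, 2 of 4 medians of other blood cell lists lay above 0. Only that of granulocyte markers did so clearly (0.22, 20 of 23 above 0). Those of megakaryocyte (0.07, 8 of 14 above 0), erythroid (−0.01) and B-lineage markers (−0.06) lay near 0. A shared loss as large as that of the natural killer and T cell genes was argued against, but a small one could not be told. A course opposite to the fasting-hormone genes was argued against as well (r = 0.07 within groups, permutation p = 0.87; r = −0.13 without the 2 farthest). Fewer such cells and a lower activity per cell were not told apart.

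Serpina3i was high in the KO libraries with low Mirg, which may come from alleles carried along with the deletion on chromosome 12. Among 388 genes within 20 Mb of Mirg 59 (15.2%) had an unadjusted p under 0.05 in KO against wild type, against 6.6% of the others, a ratio of 2.32 (Fisher's exact test, p = 3.53e-09), and none of 122 windows of 40 Mb elsewhere had more (highest 11.8%). The explanation stays open: neighbouring genes are not independent, and outside the immunoglobulin stretch the share was 9.8% (29 of 297 genes), below that highest window, with a ratio of 1.49, under the 1.5 that the test asked for (Fisher's exact p = 0.034). The shares near Mirg and elsewhere were 22.9% and 18.9% in hypoglycaemic KO alone and 12.6% and 4.7% in normoglycaemic KO alone. Over the 10 KO libraries Serpina3i followed Mirg at r = −0.9 (permutation p = 0.0023), but rho was −0.42 (permutation p = 0.23) and r was −0.38 without the 2 libraries farthest in Mirg, so that the relation rests on 2 libraries. A comparison with the genotype of the strain used for the targeting would test this.

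The median of the fasting-hormone genes lay lower in normoglycaemic KO than in wild-type livers although the glucose of these pups was not higher. In the list mean only normoglycaemic KO replicate 2 (2.013) lay below the wild-type range (2.448 to 3.203). Camera did not call the lower median with an estimated correlation (adjusted p = 0.811). That the lower glucose of these pups is the cause was argued against only weakly. Within groups the list lay higher where glucose was lower (slope −0.4 per 10 mg/dl, r = −0.75, permutation p = 0.0023, adjusted p = 0.0529, rho −0.55, r = −0.61 without the 2 farthest). This relation did not pass after adjustment, and the fit with glucose rests on it, so that it is no separate test. With glucose in the fit the median therefore moved from −0.34 to −0.8, with 27 of 28 members below 0 (camera adjusted p = 1.62e-16; adjusted p = 0.385 with an estimated correlation). Genes called in that fit were 0 (limma, smallest adjusted p = 0.0751), with 3275 at an unadjusted p under 0.05.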
